A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

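RNA levels were measured in 5 samples of yeast, 1 for each phosphate dose, each on 1 Affymetrix array. Biotin-labelled cRNA was made from 6 ug of cDNA, per the labels' protocols. The values are intensity values on a linear scale, as deposited by the authors: 1 signal per probe set and array, never negative. They come from MAS5, per the submitters' processing notes; its version, the scaling target and any filter are not given in the sources used here. The trimmed mean signal, over the values between the 2nd and the 98th percentile, was 74.0, 68.6, 69.9, 62.7 and 64.3 from 0 to 10 mM, so the arrays were not at 1 common trimmed mean. No value column was left out, and no pair of arrays held identical values. The number of arrays limits the precision.

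Probe sets were named through the platform's annotation, updated by gene identifier to the symbols of RefSeq assembly R64. Of the 9335 probe sets 6504 had 1 gene, all of which matched, 328 had several and 2503 were not listed, of which 60 were array controls. Probe sets with several genes or none were named nowhere. No coordinates are given, since no build is stated for the arrays. A background level was set at the 40th percentile of all values, 11.4 (3.52 on the log2 scale), the fallback fixed for the case that no probe sets of another organism could be identified. Values below it were set to it and log2 was taken. Probe sets of 1 gene at or above the level on at least 2 of the 5 arrays were kept, 5083 in all, and probe sets of a gene were averaged, giving 4824 genes. In 120 genes with 2 probe sets the differences between 10 and 0 mM had an SD of 0.61 (log2) between the probe sets, and in 23 they differed by more than 1. A gene below background at 1 end of the doses has a bound, given as at least N-fold, with the background level in its place; list medians hold such genes at their bound.

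With 1 array per dose there is no test between doses. A straight line in dose order (1 to 5) was fitted per gene with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (3 residual degrees of freedom, 7.64 after moderation) and Benjamini-Hochberg adjustment at 0.05 over all genes; a gene past it with a negative slope fell and with a positive slope rose. The error is the scatter of 5 arrays around a line, so a step-shaped response counts in part as error. The median residual SD after moderation was 0.33. Nothing in the labels says whether the cultures were grown in parallel. Values at 2 doses were compared as differences of log2 signal, with a minimum of 2-fold.

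For gene lists, 28 were fixed from textbook knowledge and 26 had the 3 measured genes needed for a test. Each was tested with fry on the slope (2-sided, Benjamini-Hochberg over the lists) and with camera and an estimated correlation. Fry asks whether the genes of a list move on balance one way and does not compare the list with other genes. The median difference of each list was placed among 10000 random lists of the same size, matched on mean signal in 20 bins with seed 1, as a description of these arrays. The lists were Pho4 targets, phosphate signalling and low-affinity uptake, sulfur assimilation, purine synthesis, cytosolic ribosomal proteins, ribosome biogenesis, stress genes under Msn2 and Msn4, heat shock chaperones, glycolysis, respiration and citric acid cycle, glucose-repressed genes, amino acid synthesis, iron, zinc, phospholipid and inositol, thiamine, G1/S, histones, mitosis and M/G1, a-specific and alpha-specific mating, haploid and pheromone genes, meiosis, vacuolar proteolysis and autophagy, proteasome, nitrogen catabolite repression, ergosterol and cell wall integrity. Of the 24 Pho4 targets, PHO11 and PHO12 shared a probe set, and ENA1 and CTF19 were not kept; GPP2 was listed under its older name.

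Genes were named by this rule: PHO4, TRP1 and each measured Pho4 target; the 10 genes with the largest fall and the 10 with the largest rise from 0 to 10 mM whose values at 1 and 10 mM lay on the same side of those at 0 and 0.01 mM; the 4 members of each other list with the largest difference; and, since many genes passed the trend test, the 10 with the smallest p in each direction. The groups, the tests, the lists, this rule and a set of other settings were chosen before the data were examined. Those settings were scaling of arrays to 1 median, quantile normalization, background levels at the 20th and 60th percentiles, a pseudocount of 11.4 in place of the floor, no filter on dim probe sets, a filter on mean signal, log10 dose with 0 mM set to 0.001 mM, a comparison of doses up to 0.1 mM with 1 and 10 mM, each array left out, other pairs of doses, a variance trend, and camera. Chosen after seeing the data were the comparison of 0 and 0.01 mM with the higher doses, its repeats with arrays left out or at 1 median, and scaling to the hybridisation controls or to the poly-A spike-in controls.

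The fits were tested on simulated data for 4824 genes with 50 changed genes per size. Changes along a line of 1, 2, 4 and 6 (log2, 0 to 10 mM) were found by the line in 0%, 52%, 98% and 100% of genes, with 5 false calls. Changes at a step after 0.01 mM were found by the line in 0% at each size. The comparison of 0 and 0.01 mM with the higher doses found 10%, 86%, 100% and 100% of these, with 4 false calls. Of the changes along a line it found 0%, 0%, 0% and 2%. Simulated errors were drawn for each gene on its own, so the false calls do not cover errors shared by a whole array. Even a noise-free step after 0.01 mM does not reach the 0.05 threshold on dose order before moderation. The cutoff of the adjustment depends on how many genes change, so the simulated shares need not hold for the measured data. There the line did call SPL2 and GIT1, whose drop lay between 0.01 and 0.1 mM. Each had an adjusted p = 0.0415 in limma with Benjamini-Hochberg adjustment. Fry on dose order called a list of 20 genes shifted by 2 along a line and missed one shifted by 2 at that step, which it called in the comparison of 0 and 0.01 mM with the higher doses; it called 7.2% of 500 unshifted lists without adjustment. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.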

Results

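Expression was measured in budding yeast of the W303 background that carried a MYC-tagged copy of PHO4, marked with TRP1. PHO4 encodes the transcription factor that turns on phosphate-responsive genes when phosphate is scarce. Log-phase cells spent 3 h without phosphate and then 80 min in medium with 0, 0.01, 0.1, 1 or 10 mM phosphate. Each dose was measured on 1 Affymetrix array, so there were no replicates, and differences between any pair of arrays have no replicate error. Of the 9335 probe sets, 5083 passed the filters and gave values for 4824 genes. The median signal per array was 25.5 at 0 mM, 20.6 at 0.01 mM, 19.7 at 0.1 mM, 17.0 at 1 mM and 18.4 at 10 mM, against a background level of 11.4. The ratio of the 3' to the 5' probe set of ACT1, a sign of RNA integrity, was 2.37, 3.00, 1.11, 2.19 and 2.02 from 0 to 10 mM. That of TBP was 2.63, 4.52, 2.01, 2.35 and 1.51, and both were highest at 0.01 mM.

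The series asks how targets of Pho4 respond to phosphate. Most of the measured targets were high at 0 and 0.01 mM and low at 0.1 mM and above. PHO5, which encodes a secreted acid phosphatase, had signals of 1418, 1222, 28.0, 22.0 and 24.4 from the lowest to the highest dose, a 58.0-fold difference between the ends. The high-affinity phosphate transporter gene PHO84 had 1369.9, 1157, 172, 27.8 and 27.4, a 50.04-fold difference. PHO89, for the sodium-coupled phosphate transporter, dropped in signal from 507 at 0 mM to 199 at 0.01 mM and 9.69 at 0.1 mM, and was 43.7-fold lower at 10 mM than at 0 mM. All 3 genes fell along the doses (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0395 for each). Their slopes were -1.75 ± 0.35, -1.67 ± 0.20 and -1.50 ± 0.29 (log2 per dose step, SE, 5 arrays).

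**Figure D1:**
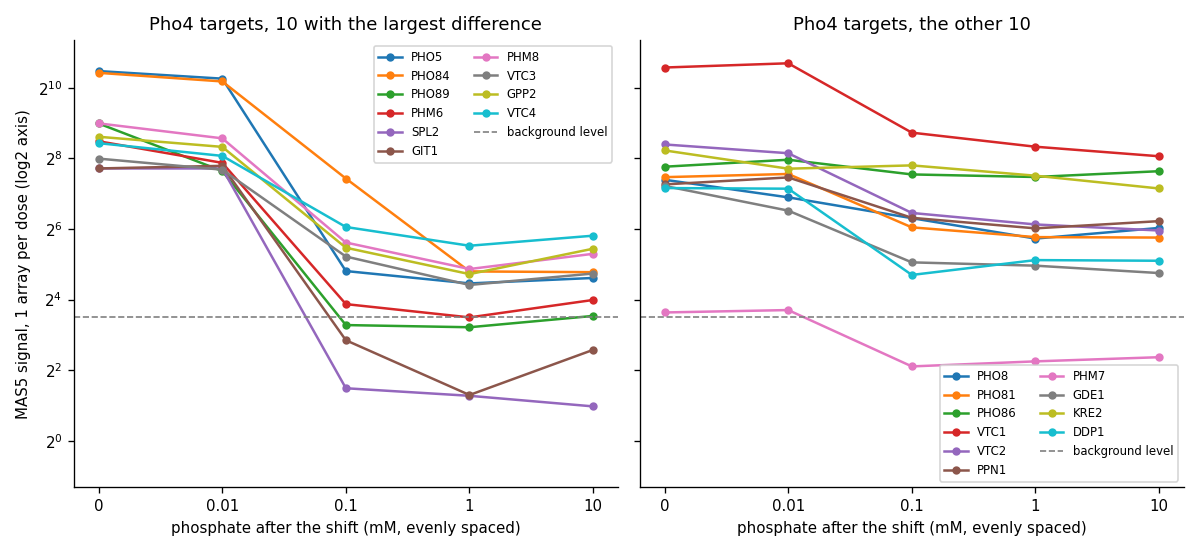
MAS5 signal (log2 axis) of the 20 measured Pho4 targets at the 5 phosphate doses in mM, spaced evenly, with 1 array per dose and the background level of 11.4 as a dashed line. Most lines are high at 0 and 0.01 mM and drop by 0.1 mM; PHO84 was still at 172 at 0.1 mM and reached 27.8 at 1 mM.

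Of the 24 fixed Pho4 targets 20 were measured, and 14 of them fell, 0 rose and 6 did not pass the test; 18 fell when adjusted over the list alone. Genes for polyphosphate synthesis fell together: VTC1, VTC2, VTC3 and VTC4, which encode the vacuolar transporter chaperone complex, were 5.71, 5.42, 9.54 and 6.15-fold lower at 10 mM than at 0 mM. The phosphatase gene PHM8 was 12.9-fold lower, PHM6 22.5-fold, and the glycerol phosphatase gene GPP2 9.0-fold. SPL2, a regulator of phosphate uptake, and GIT1, a glycerophosphoinositol transporter, were each at least 18.3-fold lower, since both were below background from 0.1 mM on. PHO81, the inhibitor of the Pho80-Pho85 kinase, fell by 1.71 on the log2 scale (adjusted p = 0.0443, limma with Benjamini-Hochberg adjustment), and the glycerophosphodiesterase gene GDE1 was 5.53-fold lower. The 6 targets that did not pass were PHO8 (vacuolar alkaline phosphatase, 2.57-fold lower), DDP1 (4.17-fold lower), PPN1 (2.06-fold lower), KRE2 (2.11-fold lower), PHO86 (1.09-fold lower) and PHM7, which stayed near background. For PHO86 the slope of -0.07 turned to 0.0437 with arrays scaled to 1 median and to 0.00792 under quantile normalization.

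The median log2 difference of the list, 10 mM minus 0 mM, was -2.57, or 5.92-fold lower, at percentile 0 among 10000 random lists of like signal, whose median was -0.17. Relative to 0 mM the list's median was -0.25 at 0.01 mM, -2.42 at 0.1 mM and -2.59 at 1 mM. For 19 of the 20 genes the largest step lay between 0.01 and 0.1 mM. Over this step the 3' to 5' ratio of ACT1 went from 3.00 to 1.11 and that of TBP from 4.52 to 2.01. Neither PHO4 (signals 62.7, 44.8, 76.3, 54.3 and 78.8) nor the marker TRP1 (110.1, 62.3, 109, 84.1 and 125) passed the test, with adjusted p = 0.573 and 0.669 in limma after Benjamini-Hochberg adjustment; the slope of TRP1, 0.08, was -0.04 without the array of 10 mM. As a list, the targets had an adjusted p = 0.0773 on dose order in limma's fry with Benjamini-Hochberg adjustment. In camera with an estimated correlation their adjusted p was 0.5995. Poly-A spike-in controls on the same arrays dropped 10.4-fold from 0 to 10 mM. Arrays scaled to equal spike-in signal gave a list median of 0.81 and left 7 of the 20 targets lower at 10 mM. This scaling shifts all genes alike, so the median relative to all genes, -2.31, could not change with it.

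Across all genes the same doses parted the arrays. Between neighbouring doses, 434 of the 4824 genes differed at least 2-fold from 0 to 0.01 mM (330 lower and 104 higher at the higher dose), 1207 from 0.01 to 0.1 mM (591 lower and 616 higher), 121 from 0.1 to 1 mM (60 and 61) and 63 from 1 to 10 mM (39 and 24). From 0 to 10 mM, 1025 genes were at least 2-fold lower and 363 at least 2-fold higher; with arrays scaled to 1 median this split was 564 lower and 771 higher, and after quantile normalization 662 and 683. The median gene differed by -0.26 (log2, 10 mM minus 0 mM) in the deposited values, 0.18 with arrays at 1 median, and 3.12 with equal spike-in signal, under which 4767 of the 4824 genes were higher at 10 mM. For each list below the median difference between 10 and 0 mM is therefore given relative to the median of all genes, called the relative median. Folds and directions of genes are those of the deposited scaling. A shift of a whole array leaves a relative median in place apart from the floor, so the scaling set beside it is quantile normalization. A line counts a step-shaped change in part as error. Counts are therefore also given for a comparison of 0 and 0.01 mM against 0.1, 1 and 10 mM (limma with Benjamini-Hochberg adjustment). It was chosen after seeing the data and is called the step comparison. Over all 4824 genes it had 1062 lower and 549 higher at the higher doses, the shares to set beside each list's counts.

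Most measured genes of the general stress response, which the factors Msn2 and Msn4 turn on, fell. Of 34 measured, 28 fell and 0 rose (32 fell adjusted over the list alone), with a median of -3.09 and a relative median of -2.83. HSP26, a small heat shock protein gene, had signals of 1121, 905, 20.4, 10.6 and 11.1 and was at least 98.04-fold lower at 10 mM. GRE1 had a signal of 748 at 0 mM, 173 at 0.01 mM and 11.03 at 0.1 mM, and was at least 65.4-fold lower; MSC1 was at least 32.9-fold and the glutamate decarboxylase gene GAD1 32.6-fold lower. Among heat shock chaperones 10 of 18 fell and 0 rose (14 adjusted over the list alone), with HSP82 at 534 and 18.5 at the ends, a 28.8-fold difference, and SSE2 11.99-fold lower. Among genes of vacuolar proteolysis and autophagy 7 of 12 fell and 0 rose (11 adjusted over the list alone), among them the vacuolar mannosidase gene AMS1 (11.8-fold), the autophagosome gene ATG8 (8.84-fold) and the aminopeptidase gene APE1 (8.0-fold). The relative medians of heat shock and of vacuolar genes were -1.64 and -1.81, and those of the 3 lists were -2.96, -2.11 and -2.43 after quantile normalization. With arrays at equal spike-in signal, which shifts all genes alike, the unadjusted medians of the 3 lists turned to 0.29, 1.48 and 1.31. Each list lay at percentile 0 of its random lists in the deposited values. In the step comparison 32 of the 34 stress genes, 13 of the 18 chaperones and 11 of the 12 vacuolar genes were lower at the higher doses and 0 higher. The 3' to 5' ratios of ACT1 and TBP also changed between 0.01 and 0.1 mM, from 3.00 to 1.11 and from 4.52 to 2.01. On dose order each list had an adjusted p = 0.0773 in fry with Benjamini-Hochberg adjustment. In camera with an estimated correlation each had an adjusted p = 0.5995. Other genes among those with the largest differences were FMP16, 37.5-fold lower, GPG1, at least 38.6-fold lower, and SIP18, at least 33.9-fold lower, and all 3 fell.

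Ribosomal protein genes were mostly higher at 10 mM than at 0 mM. Of 138 genes 81 were measured, and 22 rose, 0 fell and 59 did not pass; 72 rose and 1 fell adjusted over the list alone. RPS9A had signals of 59.0, 304, 997, 797 and 1023, a 17.4-fold difference between the ends, RPL7B was at least 16.5-fold higher at 10 mM, RPS26B 14.1-fold and RPS0B 11.5-fold. The list's median was 2.07 (relative median 2.32, or 1.99 after quantile normalization), at percentile 100 of its random lists, and 78 genes were at least 2-fold higher at 10 mM. RPL15B, named after its value was seen, was the 1 gene at least 2-fold lower (710.3 and 208). The list was already higher at 0.01 mM than at 0 mM, by a median of 1.21, in 79 of 81 genes. The array of 0.01 mM also had the highest 3' to 5' ratios of ACT1 and TBP, 3.00 and 4.52. Copies of a ribosomal protein gene are near-identical in sequence, so how the signal divides between them is uncertain. For ribosome biogenesis genes the median was -0.63 at 0.01 mM (percentile 0) and 0.71 at 0.1 mM relative to 0 mM. At 10 mM the median of the 56 biogenesis genes was 0.73 (percentile 100; relative median 0.99), and 1 rose, NOP56, which encodes a small nucleolar RNA-binding protein and was 2.97-fold higher, while 0 fell (0 passed adjusted over the list alone). For 49 of the 56 the largest step lay between 0.01 and 0.1 mM, and in the step comparison 33 were higher at the higher doses and 0 lower. Of the 81 ribosomal protein genes 66 were higher and 1 lower in that comparison. The fry test on dose order gave an adjusted p = 0.105 for ribosomal proteins and 0.211 for biogenesis after Benjamini-Hochberg adjustment. Camera with an estimated correlation gave an adjusted p = 0.5995 for each.

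**Figure D2:**
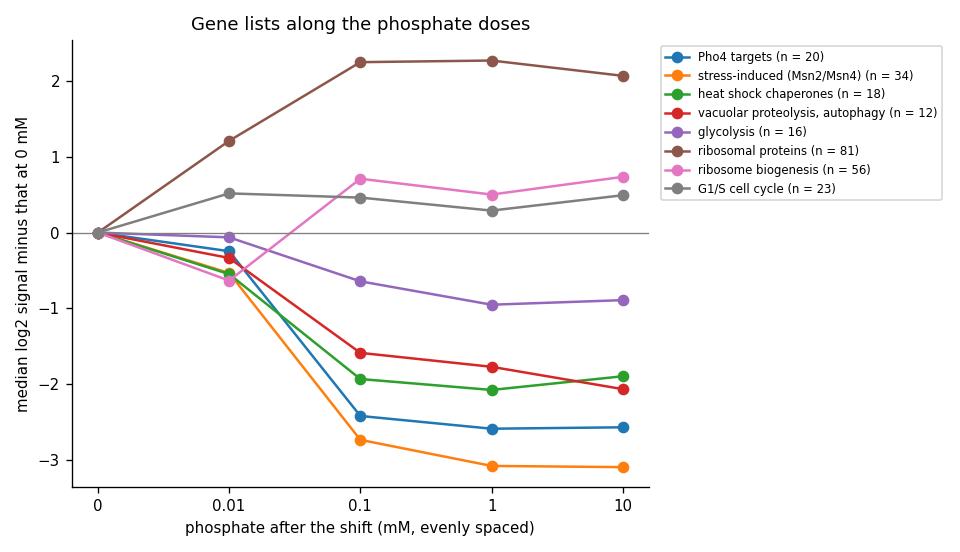
Median log2 signal of 8 gene lists minus that at 0 mM, at the 5 phosphate doses in mM, spaced evenly, with 1 array per dose and the number of measured genes in the key. Ribosomal protein genes were at 1.21 at 0.01 mM and 2.25 at 0.1 mM, while Pho4 targets were at -0.25 and -2.42; with arrays at equal spike-in signal the medians of all lists shift upward and the Pho4 list is at 0.81 at 10 mM.

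Lists of carbon and nitrogen use had different counts on dose order and in the step comparison. In glycolysis 3 of 16 fell and 0 rose (8 adjusted over the list alone; relative median -0.63, or -1.21 after quantile normalization): TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, was 17.2-fold, the enolase gene ENO1 9.90-fold and the phosphoglycerate kinase gene PGK1 4.19-fold lower at 10 mM. In respiration and the citric acid cycle 6 of 39 fell and 0 rose (7 adjusted over the list alone; relative median -0.30, or -0.46 after quantile normalization), among them COX5B (5.52-fold), KGD1 (4.31-fold), KGD2 (4.29-fold) and SDH4 (3.73-fold). Among glucose-repressed genes 4 of 18 fell and 1 rose (10 and 1 adjusted over the list alone; relative median -1.11): the hexose transporter gene HXT5 was at least 20.8-fold lower, POT1, for a peroxisomal thiolase, was 5.06-fold lower, and ATO3, a putative ammonium transporter gene, was 6.15-fold higher. Of the nitrogen catabolite-repressed genes 6 of 23 fell and 0 rose (13 adjusted over the list alone; relative median -0.82), including the glutamate dehydrogenase gene GDH2 (7.04-fold), the allantoicase gene DAL2 (at least 5.28-fold), UGA1 (4.99-fold) and the proline transporter gene PUT4 (4.77-fold). In the step comparison 10 of 16 glycolysis, 16 of 39 respiration, 9 of 18 glucose-repressed and 14 of 23 nitrogen genes were lower at the higher doses, and 1 glucose-repressed gene was higher. No list of these 4 passed on dose order: fry with Benjamini-Hochberg adjustment gave an adjusted p = 0.0917 for glucose-repressed genes and 0.0773 for each of the other lists. In camera with an estimated correlation the adjusted p was 0.617 for respiration and glucose-repressed genes and 0.5995 for glycolysis and nitrogen. In the step comparison fry gave an adjusted p = 0.0102 for glycolysis, 0.0118 for respiration, 0.0308 for nitrogen and 0.0541 for glucose-repressed genes. With arrays at equal spike-in signal the unadjusted medians of the 4 lists, in the order above, were 2.49, 2.82, 2.01 and 2.30, so the direction of each turned. This scaling shifts all genes alike, so the turn is not particular to these lists.

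Metabolic lists outside these had 0 to 3 members past the test on dose order. Of 11 genes for phosphate signalling and low-affinity uptake 1 fell, the kinase gene PHO85 (3.70-fold lower; 4 adjusted over the list alone; relative median -0.27), while its cyclin gene PHO80 had signals of 46.6 at 0 mM and 18.4 at 10 mM and did not pass. In sulfur assimilation 2 of 19 fell, MET28 and STR3 (6 adjusted over the list alone; relative median -0.37), and MET6 did not pass on dose order at 384, 470.1, 81.1, 37.8 and 78.4. In the step comparison 10 of the 19 were lower at the higher doses, MET6 among them, and the list had an adjusted p = 0.0300 in fry. On dose order its adjusted p was 0.147 in fry and 0.687 in camera with an estimated correlation. In purine synthesis 2 of 15 fell, MTD1 and ADE17, and 1 rose, the IMP dehydrogenase gene IMD2, 4.16-fold (3 and 2 adjusted over the list alone; relative median -0.35). Of 44 Gcn4-dependent amino acid genes 3 fell, LYS1 by the most, 4.63-fold (3 adjusted over the list alone; relative median -0.09, or -0.35 after quantile normalization). Of 22 iron genes 1 rose, the ferroxidase gene FET3, 4.87-fold higher at 355 (1 adjusted over the list alone; relative median -0.01, or 0.03 after quantile normalization), and its partner FTR1 did not pass at 131 and 281. Of 11 thiamine genes 1 fell, THI4, 3.52-fold (4 adjusted over the list alone; relative median -0.42). None passed among 15 zinc genes (relative median -0.22, or -0.14 after quantile normalization), 20 phospholipid genes (0.50) and 22 ergosterol genes (0.01, or -0.42 after quantile normalization), over all genes or adjusted over the list alone. In the step comparison the genes lower and higher at the higher doses were 3 and 1 for phosphate signalling, 5 and 3 for purines, 6 and 3 for amino acids and 3 and 2 for iron. They were 2 and 0 for thiamine, 2 and 1 for zinc, 2 and 4 for phospholipids and 2 and 1 for ergosterol. Over all 4824 genes they were 1062 and 549.

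Lists of growth and cell identity gave 0 to 2 members past the test on dose order. Of 32 proteasome genes 1 fell, RPN6, 2.60-fold (0 adjusted over the list alone; relative median -0.41). Of 17 cell wall genes 2 fell, PIR3, 16.5-fold, and PST1, 5.02-fold (2 adjusted over the list alone; relative median -0.14, or -0.32 after quantile normalization). Of 21 mitosis and M/G1 genes 2 fell, ASH1, 5.18-fold, and RME1, 4.91-fold (2 adjusted over the list alone; relative median -0.29). Of 4 measured histone genes 1 rose, HTB2, 4.55-fold (1 adjusted over the list alone; relative median 1.05), and copies of histone genes are near-identical, so this value is uncertain. None of 23 G1/S genes passed, over all genes or adjusted over the list alone, with a list median of 0.49 at percentile 99.99 (relative median 0.75) and 0.52 at 0.01 mM. None passed among 7 a-specific mating genes (relative median 0.19), 11 haploid and pheromone genes (-0.02, or 0.08 after quantile normalization) and 2 meiosis genes (0.13), and no alpha-specific gene was measured. In the step comparison the genes lower and higher were 8 and 0 for the proteasome, 3 and 1 for the cell wall, 4 and 0 for mitosis, 0 and 1 for histones, 0 and 1 for G1/S and 3 and 1 for a-specific genes. There were 0 for haploid and for meiosis genes. Over all 4824 genes 1062 were lower and 549 higher, and these lists were not tested against those shares.

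Poly-A spike-in and rRNA controls were lower at 10 mM than at 0 mM. The poly-A spike-in controls had a geometric mean signal of 243, 72.3, 38.9, 27.6 and 23.4 from 0 to 10 mM, with the largest step from 0 to 0.01 mM, where the Pho4 list's median was -0.25. The rRNA controls had 244, 204, 102, 75.9 and 60.4, and the hybridisation controls, which did not follow the dose, 50.8, 45.3, 43.0, 53.3 and 46.3.

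**Figure D3:**
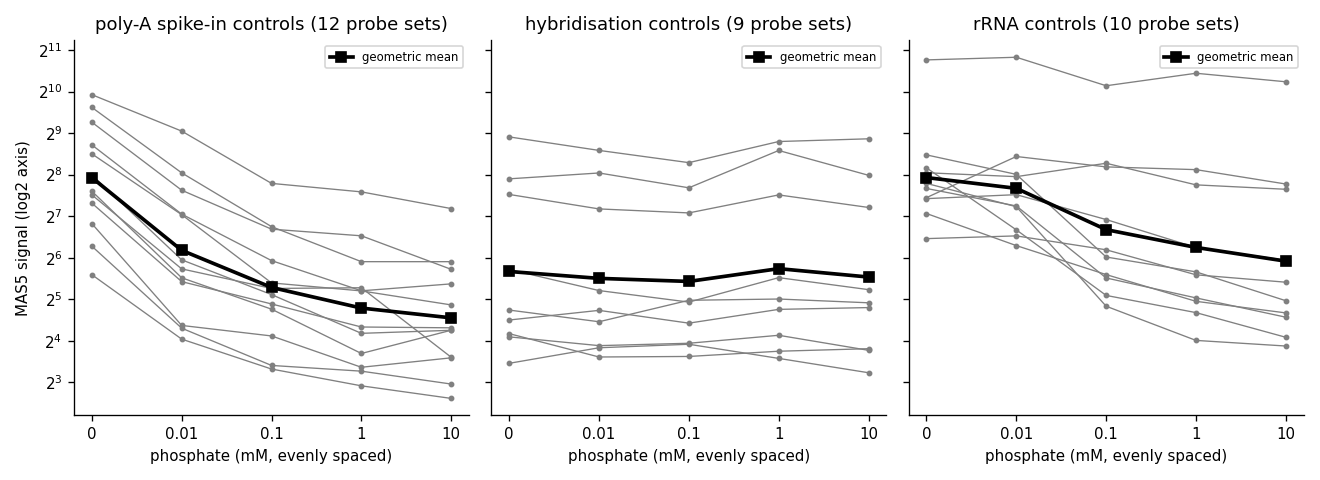
MAS5 signal (log2 axis) of each control probe set (grey) and their geometric mean (black) at the 5 phosphate doses in mM, spaced evenly, with 1 array per dose. The spike-in mean went from 243 at 0 mM to 23.4 at 10 mM, while the hybridisation mean stayed between 43.0 and 53.3.

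Along the dose order 392 of the 4824 genes fell and 56 rose (limma with Benjamini-Hochberg adjustment, adjusted p from 0.0395 to 0.0498). In the same fit 1547 genes had an unadjusted p under 0.05, where 241 is the mean number under chance. All genes share the same unreplicated arrays, so their p-values can move together. The excess over 241 therefore does not measure a departure from chance. Among the genes with the smallest p were the mitochondrial thioredoxin gene TRX3 (9.11-fold lower) and the phenylpyruvate decarboxylase gene ARO10 (7.27-fold lower). Others were the glycerol-3-phosphate dehydrogenase gene GUT2 (at least 7.68-fold lower) and the cell wall mannoprotein gene TIR1 (6.34-fold higher). The largest step lay between 0.01 and 0.1 mM for 306 of the 392 genes that fell and for 35 of the 56 that rose. The step comparison had 1062 genes lower and 549 higher at the higher doses past the threshold in limma, with 433 of the 448 trend calls among them. With arrays scaled to 1 median it had 812 lower and 1090 higher, so the balance turned with the scaling. In the deposited values 17 of the Pho4 targets were lower.

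The trend calls depended on scaling and on single arrays: with arrays scaled to 1 median 0 genes passed, and 0 passed without the array of 0 mM, of 0.01 mM or of 1 mM, while 724 fell and 226 rose without that of 0.1 mM and 449 fell and 117 rose without that of 10 mM. Slopes moved less than calls with arrays at 1 median: those of PHO5 and PHO84 were -1.63 and -1.55 against -1.75 and -1.67, and the slope of 1 of 94 named genes, PHO86, changed sign. No list passed on dose order in fry with Benjamini-Hochberg adjustment (14 of 26 had an unadjusted p under 0.05; camera with an estimated correlation gave no adjusted p below 0.5995), whereas 8 passed in the step comparison. These were the Pho4 targets (adjusted p = 0.00716), stress, heat shock, vacuolar, glycolysis, respiration, nitrogen and sulfur genes. That comparison had 557 to 819 genes lower and 256 to 306 higher without the array of 0.1, 1 or 10 mM. It had 0 lists past the threshold without that of 1 mM or of 10 mM. Without the array of 0 or of 0.01 mM, 1 array alone makes up the low doses. Those counts cannot show whether the result is stable and are left out here.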

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

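The tests in this part were chosen after the results were seen. Of the control probe sets, all 12 poly-A spike-ins and 7 of 10 for rRNA were at least 2-fold lower at 10 mM than at 0 mM, against 0 of 9 hybridisation controls. Of the 646 probe sets kept that are listed under no gene, 216 were at least 2-fold lower and 67 at least 2-fold higher at 10 mM than at 0 mM, against 1025 and 363 of the 4824 genes. 1 unlisted probe set, chosen for its large difference between 0 and 10 mM, had signals of 16.3, 2481, 3734, 2005 and 2076 from the lowest to the highest dose.

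The poly-A spike-in controls, bacterial transcripts added to RNA samples before labelling, were lower at 10 mM than at 0 mM by a mean log2 difference of -3.38 (SD 0.35 over 12 probe sets), and all 12 were lower. Their mean signal was 243 at 0 mM and 23.4 at 10 mM. The hybridisation controls, added later, differed by a mean of -0.13 (SD 0.27 over 9 probe sets), which argues against hybridisation, staining or scanning as the source. The rRNA control probe sets had a median difference of -1.94, and 7 of 10 were at least 2-fold lower, with a range from -4.08 to 0.33. A larger share of messenger RNA in the total RNA at high phosphate could lower both kinds of control, and unequal amounts of spike-in RNA could lower the spike-ins alone; the spread of the rRNA probe sets leaves both open, and they cannot be told apart.

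Among neighbouring doses, 0.01 and 0.1 mM had the most genes at least 2-fold apart, 1207, and a processing batch that parts the arrays of 0 and 0.01 mM from the others cannot be told apart from the doses, since the labels give no batch. For the Pho4 targets a batch that shifts genes of like signal alike is argued against, since the list's median step lay at percentile 0 of signal-matched lists. In 3 of the 60 orders of the 5 arrays, the real order included, at least the 448 genes of the real order passed the trend test (highest other 592), so chance is not excluded by this count. The 4 orders with the most calls, 592, 573, 448 and 350, all begin with 0 and 0.01 mM, but the other 2 orders that begin so, with 1 mM in the third place, gave 0 calls. For the comparison of 0 and 0.01 mM with the rest, the 10 splits are too few for a share under 0.05. That split had 1611 calls and the highest other 1. It was chosen after seeing that these arrays part from the others, so its lead says nothing about chance.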

How the results depend on the processing

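No paired analysis was possible because each dose has 1 array. The direction of the Pho4 list's median was the same under the other scalings, background levels, pseudocount, filters and pairs of doses chosen beforehand. Its value lay between -2.84 after quantile normalization and -2.15 with arrays at 1 median, against -2.57 in the main setting. Counts of genes along the dose order were less stable. With arrays at 1 median 0 fell and 0 rose, after quantile normalization 2 and 2, with the background level at the 60th percentile 0 and 0, without a filter 1 and 0, and with doses up to 0.1 mM against 1 and 10 mM 0 and 0. The count that rose was 88 with the background level at the 20th percentile and 90 with a pseudocount. With each array left out the counts ranged from 0 to 724 that fell and from 0 to 226 that rose. Genes at least 2-fold lower at 10 mM numbered 564 with arrays at 1 median, 662 after quantile normalization and 610 with the background level at the 60th percentile; those higher numbered 771 and 683 in the first 2 of these. Lists past the threshold of fry, 0 in the main setting, were 2 without a filter and 0 to 1 with each array left out. Of settings chosen after seeing the data, equal hybridisation controls gave 146 that rose. Equal spike-in controls gave 23 that fell, 4315 that rose, 18 genes at least 2-fold lower and 4657 higher, 20 lists and a Pho4 median of 0.81; this setting shifts each gene by the spike-in difference. The comparison of 0 and 0.01 mM with higher doses gave 1062 lower and 549 higher genes and 8 lists; with arrays at 1 median it gave 812, 1090 and 12, and without 0, 0.01, 0.1, 1 and 10 mM in turn 557, 914, 819, 557 and 709 lower, 360, 306, 287, 256 and 306 higher and 10, 16, 7, 0 and 0 lists. In that comparison, leaving out 0 or 0.01 mM leaves 1 array for the low doses. Those counts therefore cannot show whether the result is stable. Values of named genes were compared under planned settings other than log10 dose. Of these values 610 kept direction and side of the threshold, 581 lost the threshold, 25 gained it and 3 reversed. In those 3 the slope of TRP1 was -0.0365 without the array of 10 mM (range -0.0365 to 0.264 with each array left out). The slope of PHO86 was 0.0437 with arrays at 1 median and 0.00792 after quantile normalization. Log10 dose is the dose order by construction and tests nothing, so its 95 values are left out of this count. Smallest adjusted p-values of 0.0395 to 0.0498 in limma sit close to the threshold, so calls can end together; beyond that the cause was not tested. Signal over background limits dim genes. The background level was the 40th percentile of all values, so the average share of probe sets reaching it was fixed by that choice. Per array this share was 57.7% to 63.0%.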

Other observations

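The tests on ribosomal protein genes in this part were chosen after the result was seen. Classes of non-coding RNA genes were looked at after seeing the data, and differences between classes were not tested. Of 88 measured tRNA genes 10 rose and 0 fell (limma with Benjamini-Hochberg adjustment), 55 were at least 2-fold higher at 10 mM than at 0 mM, and the median difference was 1.497; 68 were higher at 0.01 mM. YNCP0022W, a tRNA gene, had signals of 13.5, 61.7, 156, 242 and 348, and YNCM0035C was at least 33.4-fold higher. Copies of tRNA genes are near-identical, so which copy gave the signal is uncertain. Of 42 small nucleolar RNA genes, which guide changes of ribosomal RNA, 2 rose and 0 fell, among them SNR72 (27.6 to 169, 6.11-fold higher), with a median of 0.65. Of 4 rRNA genes 1 fell and 0 rose, with a median of -0.79: RDN18-1, for 18S ribosomal RNA, was at least 12.2-fold lower (139, 59.3, 30.5, 18.9 and 9.10). This is the value of 1 probe set. The control probe sets for 18S ribosomal RNA differed by -0.40 to -4.08 (log2, 10 mM minus 0 mM), so the size of the change is uncertain. RDN5-1, for 5S ribosomal RNA and named outside the naming rule, did not pass at 867 and 1343. Copies of rRNA genes are near-identical too, so these values are uncertain.

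PHO84 reached its low signal at a higher dose than PHO5 and PHO89 did: 53.0% of its log2 difference between 0 and 10 mM was reached by 0.1 mM, against 96.7% for PHO5 and at least 100.4% for PHO89, whose signal at 0.1 mM lay below background. The difference was not tested. Its signal was 6.19-fold higher at 0.1 mM than at 1 mM, the second largest drop of that step among 4824 genes, and no replicate stands behind this value.

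Ribosomal protein genes had higher signal at 0.01 mM than at 0 mM, while Pho4 targets differed by a median of -0.25 at that dose. A shift of short transcripts, or of bright ones, is argued against. The list's median lay at percentile 100 of lists of other genes matched on length and at percentile 100 of those matched on signal. Each match used 1 trait alone, so a shift of transcripts both short and bright was not tested. Shared signal between copies is argued against by the 19 genes without an A or B copy, whose median was 1.00, and scaling by the lowest median relative to all genes over 5 scalings, 1.24. That value came from quantile normalization, the 1 scaling that is not a shift of whole arrays, so it alone tests this. RNA integrity stays open. The 3' to 5' ratios were 2.37 and 3.00 (ACT1) and 2.63 and 4.52 (TBP) at 0 and 0.01 mM. Any other difference between these samples, with 1 array each, stays open too, and no biological explanation was tested.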
